A study of Arabidopsis thaliana with 12 samples.

How the data were processed

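Gene expression was measured by RNA sequencing of total RNA from 14-day-old Arabidopsis thaliana seedlings grown in liquid culture under continuous light. Seedlings of the wild type Col-0 and of the mutant sid2 were treated with 20 mM L-glutamate (L-Glu) or 20 mM urea for 48 h. The samples include no untreated group. Each effect of L-Glu given here, as a rise or a fall, is therefore relative to urea, and an effect of urea cannot be told apart from it. The sid2 mutant is defective in SID2 (ICS1), which encodes isochorismate synthase, an enzyme of salicylic acid (SA) synthesis. The 4 groups held 3 libraries each and were taken from the sample titles. The genotype field of the labels gives Col-0 for all 12 samples, whereas the titles and the series design name sid2, and the titles were followed. No label says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries.

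The authors deposited one table of normalized signal, a gene-level read abundance on a count-like scale. The submitters' processing notes name TopHat2 2.1.0, TopHat, HTSeq 0.6.0, edgeR 3.22.3 and the TAIR10 genome, without a role for each. The values are not whole numbers, have no common step within a library and sum to between 2564533 and 4419987 per library, so they are neither raw counts nor CPM. How they were normalized is not stated in the sources used here. The medians of the libraries were alike, at 74.1 to 77.2, while the sums were not. The number of reads behind each library is unknown, so no interval or detection floor that needs it is given. Whether strand was used in counting is not stated in the sources used here, so reads of overlapping antisense genes may be included. Reads of near-identical paralogs, such as RBCS2B and RBCS3B or the LHCB1 genes, may have been divided between them. The table held 14897 genes. None had a value of 0 in any library, and the lowest mean over the 12 libraries was 6.93. Genes outside the table were not analysed here, among them PR1. Counts of list members below are of measured members. A gene low with urea may be in the table only because L-Glu raised it. The share of measured members that rose may therefore be too high for the whole list.

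All values were divided by one constant (3.492), which brings the mean library total to that of CPM values, and 1 scaled unit was added before taking log2. The pseudocount shrinks the fold changes of weakly expressed genes. A minimum mean of 1 scaled unit removed 0 genes. Group means were fitted with limma 3.58.1 in R 4.3.3 to all 12 libraries in one model with an intensity trend in the prior variance, which left 8 residual degrees of freedom. Tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were L-Glu against urea in each genotype, the difference between these effects (interaction term), and sid2 against Col-0 under each treatment. Named values are means ± SD of the deposited signal with n = 3 libraries, and log2 fold changes are given with the standard error (SE) of the fit.

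The fit was tested on simulated data that had the means and residual spreads of the real genes, with 200 of the 14897 genes changed. For L-Glu against urea in Col-0, 100% of the genes changed by 2 on the log2 scale were recovered, 41.8% of those changed by 1 and 0% of those changed by 0.5, with 7 false calls. For the interaction these shares were 86.6%, 2.99% and 0%, with 2 false calls. In the real Col-0 comparison 8946 genes were called, 5999 of them by at least 2-fold, so smaller changes were called too. With so many changed genes the adjustment is less strict. The shares simulated for L-Glu against urea therefore do not apply to the real comparisons of the treatments.

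Comparisons, tests, gene lists, the rule for named genes and all alternatives except those named as later additions were set before the data were examined. The 23 gene lists had 337 members, of which 239 had values. Lists with at least 3 measured members (22 lists) were tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists, and again with an estimated correlation and with fry. The list of seed storage markers had 0 of 5 members measured and was not tested. The rule for named genes had 4 parts. SID2 and PR1 were to be named in each comparison. In each comparison the 5 highest and 5 lowest log2 fold changes were named among genes past the threshold with a mean of at least 5 scaled units and no overlap between the compared groups, a condition not used for the interaction. Up to 4 members of each list with the smallest p in the Col-0 comparison were named there and in the other comparisons. For the interaction and the genotype comparisons, the 2 members with the smallest p were added for each list with at least 1 call. The text prints a selection of these genes. Symbols came from the TAIR10.1 annotation, which held 14819 of the 14897 identifiers. It was used only for names and for the order of neighbouring genes, and no coordinates are given, since the processing notes name TAIR10.

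The highest correlation between any 2 libraries was 0.978, so no library was a duplicate of another. Deviations of same-numbered libraries from their group means correlated at 0.116, 0.287 and 0.204 between treatments in sid2, and at 0.126, 0.219 and 0.196 between genotypes under urea. All exceeded 0.1, and the numbers were taken to pair the libraries in these comparisons. The values were 0.086, 0.026 and 0.062 between treatments in Col-0, and 0.142, -0.110 and 0.112 between genotypes under L-Glu, where the numbers were not taken as pairs. In Col-0, 3 of 3 urea libraries were still best matched by the L-Glu library of their own number, so a weak pairing is not excluded. Between genotypes under L-Glu this held for 2 of 3 Col-0 libraries. The alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 scaled units, median-ratio rescaling, quantile normalization, the replicate number as a block, a fit to the compared groups alone, a prior variance without trend, a robust prior, library weights, removal of organelle genes, a fold limit of 2, and omission of each library in turn. The alternative without a filter is void because the filter removed no gene, and alternatives for raw counts were not used. Scaling each library to one total, the protein families and the runs of neighbouring genes were added after the data had been seen.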

Results

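The data comprised normalized read abundances of 14897 genes in 12 libraries from Arabidopsis seedlings. Col-0 with urea, Col-0 with L-Glu, sid2 with urea and sid2 with L-Glu were each represented by 3 libraries. The deposited signal summed to 2668836 ± 98784 (SD, n = 3) per library in Col-0 with urea, 4221476 ± 280645 in Col-0 with L-Glu, 2894246 ± 140844 in sid2 with urea and 4183879 ± 149142 in sid2 with L-Glu. The 100 most abundant genes held 18.9% ± 0.955 (SD, n = 3) of the signal in Col-0 with urea and 26.2% ± 2.34 in Col-0 with L-Glu. In sid2 they held 22.1% ± 1.85 with urea and 26.7% ± 0.665 with L-Glu. Chloroplast and mitochondrial genes held 1.16% ± 0.450 and 0.605% ± 0.239 in Col-0, and 1.37% ± 0.0615 and 0.448% ± 0.0518 in sid2, with urea and L-Glu respectively.

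Across genes, log2 values correlated at 0.926 to 0.968 between libraries of Col-0 with urea, at 0.951 to 0.960 for Col-0 with L-Glu, at 0.963 to 0.970 for sid2 with urea and at 0.973 to 0.978 for sid2 with L-Glu. Between treatments the correlation was 0.412 to 0.504. Between genotypes it was 0.923 to 0.970 under urea and 0.90 to 0.957 under L-Glu. The first principal component carried 85.7% of the variance and parted the treatments. Col-0 urea library 1 lay apart on the third component, which carried 2.62% of the variance, at 56.6 against -9.20 and -11.9 for the other libraries of its group. Col-0 L-Glu library 2 lay at 52.0 on the second component, against 21.4 and 24.0.

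**Figure D1:**
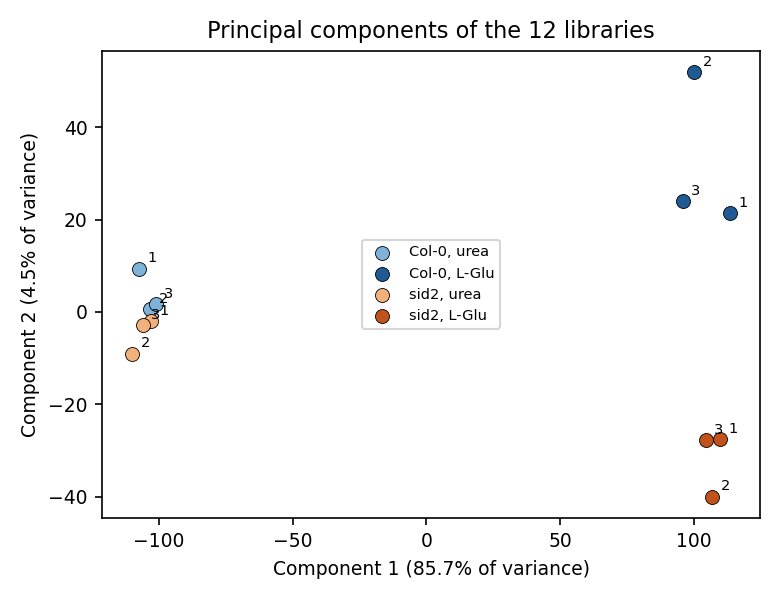
Scores of the 12 libraries on principal components 1 and 2 (arbitrary units), with the share of variance on each axis. Each point is a library, colours mark the 4 groups and numbers the replicate. Component 1 parts urea from L-Glu, and component 2 (4.54% of variance) parts the genotypes under L-Glu.

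The first comparison asked which genes differed between L-Glu and urea in the wild type. In Col-0, transcripts of immune and stress signalling were higher with L-Glu than with urea, and those of photosynthesis were lower. WRKY30, a transcription factor gene, rose from 4.26 ± 2.77 (SD, n = 3) with urea to 12960 ± 1998 with L-Glu, a log2 fold change of 10.77 (SE 0.251, adjusted p = 1.12e-16). Its urea values lay near the lowest of these libraries (0.113 to 3.11), so the size of this fold change is poorly measured. OXI1, a kinase gene of oxidative stress signalling, rose by a log2 fold change of 10.15 (SE 0.305) and CML37, which encodes a calmodulin-like protein, by 10.12 (SE 0.311). The uncharacterized genes AT2G18193 and AT1G13480 rose by 10.50 (SE 0.356) and 10.04 (SE 0.222). Among the named genes the largest decreases were those of RBCS2B and RBCS3B, which encode small subunits of Rubisco, at -8.84 (SE 0.635) and -8.29 (SE 0.482). The Rubisco activase gene RCA fell from 30280 ± 3774 to 154 ± 8.88 (log2 fold change -7.58, SE 0.309, adjusted p = 1.22e-13). GOX1, a glycolate oxidase gene of photorespiration, and FBA2, a plastid aldolase gene, changed by -7.58 (SE 0.382) and -7.56 (SE 0.391).

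All 9 measured members of the list of SA synthesis and the EDS1 node rose, with a median log2 fold change of 5.62. SID2 itself rose from 96.0 ± 5.60 (SD, n = 3) to 9324 ± 1736 (log2 fold change 6.54, SE 0.235, adjusted p = 2.50e-14). PBS3, which acts after SID2 in SA synthesis, changed by 7.61, the isochorismate exporter gene EDS5 by 6.11 and SARD1, a transcriptional activator of SID2, by 6.44. Of 10 measured SA response genes (20 in the list), 9 rose and 1 was not called. They included WRKY46 at 8.88, WRKY53 at 6.20, WRKY54 at 3.77 and the SA receptor gene NPR1 at 3.58. All 24 measured genes of pattern-triggered immunity (28 in the list) rose, with a median of 4.54. Among them were the peroxidase gene PER4 at 9.33, NHL10 at 6.39 and the chitin receptor gene LYK5 at 5.77. The camera test called the lists of SA synthesis and the EDS1 node (adjusted p = 5.17e-07), SA response (9.16e-06) and pattern-triggered immunity (1.81e-15). None of the 10 list calls in this comparison held when the correlation was estimated, and here these were adjusted p = 0.0724, 0.0722 and 0.0615 with an estimated correlation.

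Of 14 genes of jasmonate synthesis and the MYC branch, 12 rose and 1 fell, and 13 rose when adjusted over the list alone. The lipoxygenase genes LOX4 and LOX3 changed by 8.71 and 5.78 on the log2 scale and the repressor genes JAZ5 and JAZ1 by 7.16 and 3.90 (camera adjusted p = 1.55e-06, adjusted p = 0.0722 with an estimated correlation). Among 10 ethylene and ERF genes 6 rose and 1 fell, with ACS6, an ethylene synthesis gene, at 6.85 and ERF6 at 6.00 (camera adjusted p = 0.00861, adjusted p = 0.266 with an estimated correlation). Of 14 camalexin and indole glucosinolate genes, 8 rose and 1 fell, with IGMT2 at 8.12, CYP79B2 at 2.47 and PEN2 at 2.78 (camera adjusted p = 0.00640, adjusted p = 0.0878 with an estimated correlation). Of 13 genes of glutathione transferases and oxidative stress, 11 rose and 1 fell. They included the glucosyltransferase gene UGT74E2 at 9.72, ZAT12 at 7.39 and the alternative oxidase gene AOX1A at 5.60 (camera adjusted p = 6.15e-05, adjusted p = 0.0722 with an estimated correlation). All 5 measured heat shock genes (9 in the list) rose (camera adjusted p = 0.000326, adjusted p = 0.190 with an estimated correlation). The small heat shock protein gene HSP17.6A was at 7.48 and the disaggregase gene HSP101 at 5.42. Of 9 clock genes, 7 rose and 1 fell, and 8 rose when adjusted over the list alone, with PRR9 at 3.72 and PRR5 at 2.83. The clock call (camera adjusted p = 0.0179) gave adjusted p = 0.113 with an estimated correlation, and quantile normalization ended it (adjusted p = 0.105).

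All 22 measured nuclear photosynthesis genes fell, with a median log2 fold change of -4.73. Besides RCA and the RBCS genes they included PETC, which encodes the Rieske protein, at -5.93, and the light-harvesting genes LHCB5 at -5.61 and LHCB6 at -4.70 (camera adjusted p = 1.81e-15, adjusted p = 0.0724 with an estimated correlation). Among 21 genes of glutamate, glutamine, asparagine and proline metabolism, 5 rose and 10 fell (camera adjusted p = 0.196). The glutamate decarboxylase gene GAD4 rose by 9.06, whereas GLU1 and GS2, which encode the plastid enzymes of ammonium assimilation, changed by -7.33 and -5.46 and GAD2 by -2.74. Of 17 genes of nitrate, ammonium and urea uptake and reduction, 6 rose and 9 fell, so that the list median (-0.81) and mean (0.02) had opposite signs (camera adjusted p = 0.641). The amino acid transporter gene LHT1 rose by 3.2, the nitrate uptake gene NRT3.1 by 4.21 and the ammonium transporter gene AMT2 by 3.53. Among 10 glutamate receptor-like genes 4 rose and 1 fell, with GLR2.5 at 4.08, GLR1.2 at 3.58, GLR1.3 at 3.51 and GLR3.4 at -1.12. The camera test did not call this list (adjusted p = 0.489), whose median (-0.21) and mean (0.88) differed in sign.

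Of 9 aliphatic glucosinolate genes, 1 rose and 5 fell, with the regulator gene MYB28 at -2.42 and CYP83A1 at -1.66 (camera adjusted p = 0.210). Among 11 senescence genes 4 rose and 5 fell. WRKY6 and SAG21 changed by 3.61 and 2.43 and the chlorophyll breakdown genes NYC1 and NYE1 by -3.02 and -2.74 (camera adjusted p = 0.491). In the list of abscisic acid and dehydration 5 of 6 genes rose, with KIN2 at 3.35 (camera adjusted p = 0.103). Of 8 sulfate assimilation genes 7 rose and 1 fell, with APR3 at 2.25 and APR2 at -1.61 (camera adjusted p = 0.111). Of 4 phosphate starvation genes 3 rose, including SPX1 at 1.90 (camera adjusted p = 0.180), and of 4 iron genes 2 rose and 1 fell, with FRO2 at 4.27 and FER4 at -2.69 (camera adjusted p = 0.557). Of 5 cell division genes CDKB2;1 rose by 2.03 and KN changed by -2.18 (camera adjusted p = 0.986). Among 8 root cell type markers 3 rose and 1 fell, 2 and 1 when adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.986). BGLU23 was at 1.07 there but at -0.15 after quantile normalization, and MYB36 was at 0.58 but at -0.01 when each library was scaled to one total, and its call was ended by 10 of the 12 omissions of a library. Of 6 control genes, ACT2 and ACT8 fell by 1.37 and 0.933 on the log2 scale and 4 were not called, with PP2AA3 at 0.20, or at -0.44 when each library was scaled to one total (camera adjusted p = 0.491). For the lists of this comparison without a separate count, the counts adjusted over the list alone equalled those over all genes.

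In total 8946 of 14897 genes (60.1%) changed in Col-0, 4426 upwards and 4520 downwards, and 5999 of them by at least 2-fold. The balance of directions rested on the scale of the deposited values. When each library was scaled to one total, the median over all genes moved from -0.05 to -0.66 and 26% of the called genes rose, against 49.5% on the deposited scale. Quantile normalization moved that median to -0.14.

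**Figure D2:**
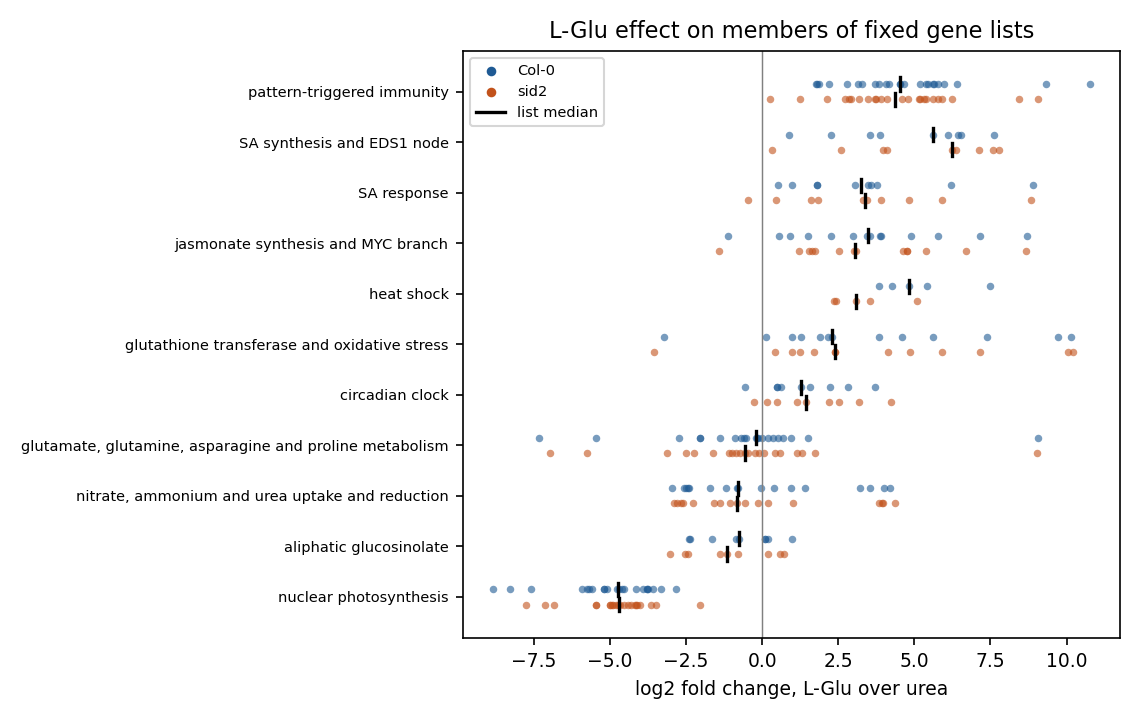
Log2 fold change of L-Glu over urea (x axis) for each measured member of 11 gene lists (y axis) in Col-0 and sid2, with black bars at the list medians. All photosynthesis genes lie below 0 in both genotypes, with medians of -4.73 and -4.71, and the medians of pattern-triggered immunity lie at 4.54 and 4.36.

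The same comparison in sid2 asked which responses to L-Glu were present in the SA synthesis mutant. AT2G18193 rose from 27.2 ± 16.8 (SD, n = 3) to 46870 ± 7924, a log2 fold change of 10.76 (SE 0.356, adjusted p = 8.08e-15). UGT74E2 and the cytochrome P450 gene CYP81D8 both rose by 10.20, OXI1 by 10.04 and BCS1, a mitochondrial ATPase gene, by 9.66. RBCS2B changed by -7.77, RBCS3B by -7.15, GLU1 by -6.97, FBA2 by -6.87 and RCA by -6.83. The SID2 transcript rose from 46.2 ± 17.9 to 6731 ± 1136 (log2 fold change 7.13, SE 0.235, adjusted p = 7.68e-15).

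Of the list of SA synthesis and the EDS1 node 8 of 9 genes rose in sid2, including PBS3 at 7.59 and EDS5 at 6.36, and of the SA response list 8 of 10 rose, with WRKY46 at 8.84. WRKY54, which changed by 3.77 in Col-0, was at 0.46 in sid2 (adjusted p = 0.103), where its signal lay near the lowest values of the libraries. Among 24 genes of pattern-triggered immunity 23 rose, and all 22 photosynthesis genes fell. All 5 heat shock genes rose, with HSP101 at 3.07. Of the jasmonate list 13 of 14 genes rose and 1 fell, with LOX4 at 8.67 and LOX3 at 4.75. Of the ethylene and ERF list 8 of 10 rose, of the oxidative stress list 11 of 13 rose and 1 fell, and of the clock list 7 of 9 rose. In the camalexin list 8 of 14 genes rose and 2 fell, which camera did not call (adjusted p = 0.0594). The 9 lists called by camera were those called in Col-0 except the camalexin list, and their adjusted p-values ranged upwards from 0.0907 with an estimated correlation, so that 0 calls held. Counts adjusted over the list alone equalled those over all genes for these lists. Quantile normalization ended the clock call (adjusted p = 0.0710).

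In sid2 9592 genes (64.4%) changed, 4761 upwards and 4831 downwards, and 6678 of them by at least 2-fold. The libraries were paired by their numbers in this comparison, and 9775 genes were called with the replicate block. With each library scaled to one total, 31.2% of the called genes rose against 49.6% on the deposited scale, and the median over all genes moved from -0.02 to -0.52. Across the 14897 genes, which are not independent replicates, the L-Glu effects in Col-0 and sid2 correlated at Pearson's r = 0.945 and Spearman's rho = 0.902. Both genotypes shared 3758 genes that rose, where independence gives 1415, and 3752 that fell, where it gives 1466. The effects were called in opposite directions for 41 genes, where independence gives 2880.

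The interaction asked for which genes the response to L-Glu differed between the genotypes. WRKY54, a transcription factor gene of SA signalling, had the largest difference among the named genes, with a log2 fold change of 3.77 in Col-0 and 0.46 in sid2, a difference of -3.31 (SE 0.344, adjusted p = 0.000184). In sid2 it lay at 5.68 to 12.4, near the lowest values of these libraries (1.37 to 5.10). The pseudocount of 3.49 deposited units shrinks fold changes there, so its response in sid2 is poorly measured. AT3G22620 changed by 0.64 in Col-0 and -2.45 in sid2 (difference -3.09, SE 0.480). GATA17, a GATA factor gene, changed by 0.34 and 3.17 (difference 2.83, SE 0.409, adjusted p = 0.00685), and TRM82 by -0.17 and 2.44 (difference 2.61, SE 0.393). FIB2, which encodes a fibrillarin of the nucleolus, changed by -1.54 in Col-0 and 1.01 in sid2 (difference 2.55, SE 0.473). Among further genes with a larger response in Col-0, AT4G15990 differed by -2.61 and WRKY30 by -1.72. With urea WRKY30 lay near the lowest values in both genotypes, so its difference rests on the L-Glu libraries, where sid2 was at -1.72 against Col-0. AT2G15020 fell further in Col-0, by -3.13 against -0.48 in sid2 (difference 2.65). AT3G19680 changed by 0.57 in Col-0 and 3.04 in sid2 (difference 2.47), and WRKY18 by 1.79 and 3.43 (difference 1.64). For SID2 the difference was 0.60 (SE 0.333, adjusted p = 0.373).

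All 5 heat shock genes had smaller estimates in sid2, with a median difference of -1.86, and 3 were called, or 5 when adjusted over the list alone. HSP101 differed by -2.35 (SE 0.449), HSP90.1 by -1.86 and HSP70 by -1.49, and Hsp70b, outside the list, by -2.46. The list gave a camera adjusted p = 6.89e-05 and adjusted p = 0.452 with an estimated correlation, and fry did not call it (adjusted p = 0.0817). HSP101 reached 1756, 3895 and 1175 in the Col-0 L-Glu libraries, with the highest value in library 2, and 547 to 676 in the sid2 L-Glu libraries. The root cell type markers had a median difference of -0.69 with 0 genes called and 1 when adjusted over the list alone (camera adjusted p = 0.0477, adjusted p = 0.405 with an estimated correlation). Fry called this list too (adjusted p = 0.0275). The camera call was also ended by a pseudocount of 0.1 (adjusted p = 0.0527), by quantile normalization (0.0610) and by 6 omissions. These were Col-0 urea library 3 (0.0994), Col-0 L-Glu libraries 1 (0.0705) and 3 (0.123), sid2 urea libraries 1 (0.0665) and 2 (0.0503), and sid2 L-Glu library 3 (0.151). In other lists the jasmonate gene LOX3 rose by 5.78 in Col-0 and 4.75 in sid2 (difference -1.03). The nitrite reductase gene NIR1 fell further in sid2, at -1.73 in Col-0 and -2.89 in sid2 (difference -1.16). So did LHCB1.1, at -3.32 and -4.67 (difference -1.35), and AMT1;2, at -0.03 and -1.385 (difference -1.36). The senescence gene SAG13 was at -0.41 and 1.36 (difference 1.77). The remaining lists were not called by camera.

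The interaction called 291 genes, of which 191 had a higher effect in sid2 and 100 a lower one, and 2511 genes had an unadjusted p under 0.05. This count rested on single libraries, as it was 9 without sid2 L-Glu library 2, 41 without sid2 urea library 3 and 43 without Col-0 L-Glu library 2. It was 65 and 179 without sid2 urea libraries 1 and 2, 98 and 107 without sid2 L-Glu libraries 3 and 1, and 108 without Col-0 urea library 2. WRKY54, GATA17, TRM82 and AT3G22620 kept their calls without any one of the 12 libraries. The calls of Hsp70b and FIB2 were ended by 1 of the 12 omissions each, those of HSP101 by 2, AT3G19680 by 3, WRKY30 by 4, WRKY18 and AT2G15020 by 5, AT4G15990 by 6, HSP90.1 and SAG13 by 7, HSP70 and LHCB1.1 by 8, NIR1 and AMT1;2 by 10 and LOX3 by 11. With each library scaled to one total, 82.9% of 415 called genes had a higher effect in sid2, against 65.6% on the deposited scale.

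Under urea, the comparison of sid2 with Col-0 asked which transcripts differed without L-Glu. Genes of SA signalling were among those lower in sid2. WRKY54 was at 48.8 ± 5.30 (SD, n = 3) in Col-0 and 6.77 ± 1.25 in sid2 (log2 fold change -2.35, SE 0.243, adjusted p = 0.000168). WRKY70 was at 299 ± 100 and 65.3 ± 7.90 (log2 fold change -2.08, SE 0.263, adjusted p = 0.00180), and SARD1 at 49.5 ± 10.1 and 11.9 ± 7.11 (log2 fold change -1.86, SE 0.261, adjusted p = 0.00382). GLP9, a germin-like protein gene, differed by -1.89 and SAG13 by -1.86. The glutamate receptor-like genes GLR1.2 and GLR2.5 differed by -1.26 and -1.06. SID2 was at 96.0 ± 5.60 in Col-0 and 46.2 ± 17.9 in sid2 (log2 fold change -1.06, SE 0.235, adjusted p = 0.0745). With the replicate number as a block in the fit to all 12 libraries this was adjusted p = 0.0275. That fit also blocks the groups whose numbers were not taken as pairs. With the block in the urea libraries alone, 1 gene in all was called.

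Higher in sid2 were AT4G22470 at 1.37, TPLATE, which encodes a subunit of an endocytic adaptor complex, at 1.16, the peroxiredoxin gene 2-Cys Prx B at 1.1, the sulfite oxidase gene SOX at 1.09, AT3G01860 at 1.08 and the aquaporin gene TIP2;3 at 1.05. TPLATE, AT3G01860 and SOX lie in 1 run of 16 neighbouring measured genes on chromosome 3, all of them with higher estimates in sid2. Of 10 SA response genes 3 were lower, or 6 when adjusted over the list alone, with a median of -0.75. The camera call of this list (adjusted p = 5.01e-13) held with an estimated correlation (adjusted p = 0.0147). Camera called 14 of the 22 lists, and the other 13 calls were lost with an estimated correlation. The list of SA synthesis and the EDS1 node had 1 lower gene, or 4 when adjusted over the list alone, and a median of -0.41 (camera adjusted p = 5.68e-05, adjusted p = 0.121 with an estimated correlation). The photosynthesis list had a median of 0.41 and 0 called genes (camera adjusted p = 3.58e-06, adjusted p = 0.211 with an estimated correlation, fry adjusted p = 0.177). Of the 14 calls, 9 held without any one library. Without Col-0 urea library 1 those of pattern-triggered immunity (adjusted p = 0.219), abscisic acid (0.218), heat shock (0.210) and sulfate assimilation (0.379) were lost. Without Col-0 urea library 3 those of pattern-triggered immunity (0.0818) and root markers (0.180) were lost, and without sid2 urea library 1 those of pattern-triggered immunity and heat shock (both 0.0518).

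Under urea 37 genes passed the threshold, 10 higher and 27 lower in sid2, and 943 had an unadjusted p under 0.05. The excess of lower genes rested on single libraries, with 19 higher and 18 lower without Col-0 urea library 3 and 10 of each without Col-0 urea library 2. The libraries were paired by number here. With the replicate block 49 genes were called in the fit to all libraries, but 1 in the fit to the urea libraries alone. The count was 13, 16 and 21 without sid2 urea libraries 1, 2 and 3, 20 without Col-0 urea library 2, 22 and 24 without sid2 L-Glu libraries 1 and 2, and 5 when the urea libraries were fitted alone without the block. With each library scaled to one total, 60 genes were called, of which 13.3% were higher in sid2, against 27.0% on the deposited scale. In the fit to all groups, WRKY54, WRKY70, GLP9, SAG13, SARD1 and SOX kept their calls without any one of the 12 libraries. Not all of them can have kept their calls in the urea libraries alone, where 5 genes in all were called. The call of TPLATE was ended by 1 of the 12 omissions, that of GLR1.2 by 3, 2-Cys Prx B by 5, AT4G22470 by 6, GLR2.5 and AT3G01860 by 10 and TIP2;3 by 11.

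**Figure D3:**
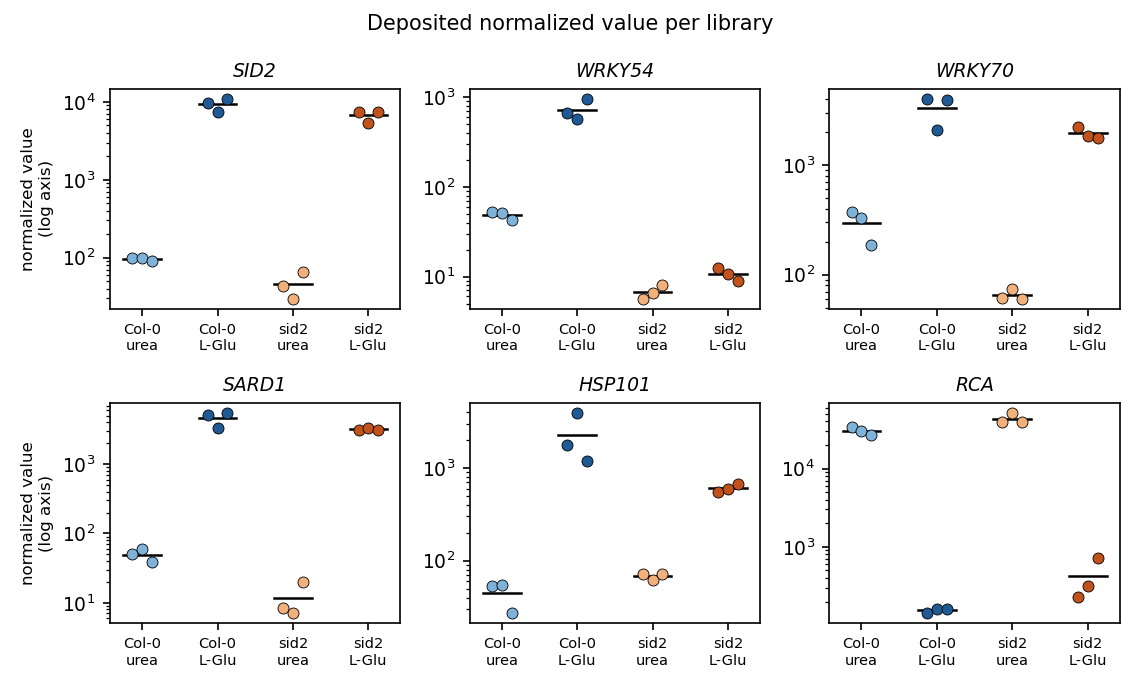
Deposited normalized value (y axis, log scale, not starting at 0) of 6 genes in each library of the 4 groups (x axis). Points are libraries and bars are group means with n = 3. WRKY54 lies at 5.68 to 12.4 in all sid2 libraries, below all Col-0 libraries, and SID2 rises with L-Glu in both genotypes.

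Under L-Glu, the comparison of sid2 with Col-0 asked which transcripts differed after the treatment. WRKY54 was at 726 ± 202 (SD, n = 3) in Col-0 and 10.7 ± 1.79 in sid2 (log2 fold change -5.66, SE 0.243, adjusted p = 5.28e-11). AT3G22620 differed by -2.35, the cysteine protease gene CEP1 by -2.32, RWP1, an acyltransferase gene of suberin synthesis, by -2.27 and AT4G33610 by -2.17. Higher in sid2 were AT2G15020 at 3.59 (SE 0.405, adjusted p = 7.45e-05), ELIP1, an early light-induced protein gene, at 2.93 (SE 0.298, adjusted p = 2.20e-05), CML41 at 2.8, the kinase gene CIPK20 at 2.55 and AT1G64500 at 2.52. SID2 differed by -0.47 (SE 0.235, adjusted p = 0.197).

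Of 10 SA response genes 3 were lower and 1 higher, or 6 and 1 when adjusted over the list alone, with DMR6 at -1.19 and WRKY53 at -0.87 (camera adjusted p = 0.00400, adjusted p = 0.352 with an estimated correlation). Of 24 genes of pattern-triggered immunity 5 were lower and 2 higher, or 8 and 2 when adjusted over the list alone, with WRKY30 at -1.72 and LYK5 at -1.46 (camera adjusted p = 0.00612, adjusted p = 0.396 with an estimated correlation). Leaving out Col-0 L-Glu library 1 ended this call (adjusted p = 0.114). Of 14 camalexin and indole glucosinolate genes 6 were lower, or 7 when adjusted over the list alone, with IGMT2 at -1.18 and CYP83B1 at -0.84 (camera adjusted p = 0.000474, adjusted p = 0.116 with an estimated correlation). Of 5 heat shock genes 4 were lower, with HSP101 at -1.73 and HSP90.1 at -1.60 (camera adjusted p = 0.000724, adjusted p = 0.396 with an estimated correlation). Of 22 photosynthesis genes 7 were higher and 1 lower, or 8 and 1 when adjusted over the list alone, with LHCB2.1 at 1.32 and PETC at 1.3 (camera adjusted p = 0.000474, adjusted p = 0.437 with an estimated correlation, fry adjusted p = 0.0739). Of 9 clock genes 5 were higher, with PRR9 at 1.27 and LUX at 0.98 (camera adjusted p = 0.00168, adjusted p = 0.116 with an estimated correlation). In lists without a camera call, the nitrate reductase gene NIA2 was at 1.36, the asparagine synthetase gene ASN3 at 1.33, JAZ9 at 1.26, GLR1.3 at -1.28 and PR3 at -1.14.

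Under L-Glu 1983 genes (13.3%) differed, 1083 higher and 900 lower in sid2, and 895 of them by at least 2-fold. The count was 792 without sid2 L-Glu library 2, 838 without Col-0 L-Glu library 2 and 1284 without sid2 L-Glu library 1. The call of AT4G33610 was ended by 3 of the 12 omissions and that of WRKY53 by 5. Between the treatments, 7 genes were higher in sid2 in both, of which 6 lie in the run on chromosome 3 and the seventh is 2-Cys Prx B, so they are not independent. Lower in both were 9 genes, where independence gives 1.63. Across genes, the genotype effects under urea and under L-Glu correlated at r = 0.146.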

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

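The counts of other splits, and the use of the omissions and of the fits to single treatments as tests of an explanation, were chosen after the result was seen.

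The response to L-Glu differed between sid2 and Col-0 for 291 genes by the interaction term, and each named gene below was noted for that reason. The differences (sid2 minus Col-0, log2) were -3.31 for WRKY54, -3.09 for AT3G22620, -2.61 for AT4G15990, -2.46 for Hsp70b, -2.35 for HSP101, -1.86 for HSP90.1, -1.72 for WRKY30, -1.49 for HSP70, -1.36 for AMT1;2, -1.35 for LHCB1.1, -1.16 for NIR1 and -1.03 for LOX3. They were 2.83 for GATA17, 2.65 for AT2G15020, 2.61 for TRM82, 2.55 for FIB2, 2.47 for AT3G19680, 1.77 for SAG13, 1.64 for WRKY18 and 1.32 for CYP81D8. For SAG13 and CYP81D8 the genotypes differed under urea, by -1.86 and -1.56 (limma adjusted p = 0.00672 and 0.00319). Under L-Glu they were at -0.09 and -0.24 and not called. WRKY54 lay near the lowest values of the libraries in sid2, so its response there is poorly measured. WRKY30 lay near them with urea in both genotypes, so the sizes of its responses are poorly measured too. The calls of WRKY54, AT3G22620, GATA17 and TRM82 held without any one library, whereas those of Hsp70b and FIB2 were ended by 1 of the 12 omissions each, HSP101 by 2, AT3G19680 by 3, WRKY30 by 4, WRKY18 and AT2G15020 by 5, AT4G15990 by 6, HSP90.1 and SAG13 by 7, HSP70, LHCB1.1 and CYP81D8 by 8, NIR1 and AMT1;2 by 10 and LOX3 by 11.

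The interaction count of 291 was 9 without sid2 L-Glu library 2, 107 and 98 without sid2 L-Glu libraries 1 and 3, 65, 179 and 41 without sid2 urea libraries 1, 2 and 3, 108 without Col-0 urea library 2 and 43 without Col-0 L-Glu library 2. In 8 of 100 drawn splits of the libraries into genotypes within each treatment, the real one included, at least 291 genes were called, and the highest other split called 853. By this share chance was not excluded. All 8 kept the L-Glu libraries split by genotype, as 10 of the drawn splits did, and the other 90 called at most 0. High counts were thus seen only where the genotype division of the L-Glu libraries was kept, which was not enough in all 10 such splits. Since these splits retained it, they are no relabelling without an effect and the share decides little.

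The count of genes that differed between genotypes was 1983 under L-Glu and 37 under urea. A deviating Col-0 urea library was weighed as a technical explanation, but without Col-0 urea library 1 the count under urea was 27. Without Col-0 L-Glu library 2 the count under L-Glu was 838, and it was 1284 and 792 without sid2 L-Glu libraries 1 and 2, while the count under urea was 13, 16 and 21 without sid2 urea libraries 1, 2 and 3, 20 without Col-0 urea library 2, and 22 and 24 without sid2 L-Glu libraries 1 and 2. The high count under L-Glu did not need a spread estimate shared by all groups, since 2256 genes were called in the L-Glu libraries alone. In the urea libraries alone 5 were called. That fit held Col-0 urea library 1, which lay apart and may widen the spread, so a lower power under urea is not excluded. An L-Glu response that depends on the genotype may account for part of the difference, as a hypothesis. A culture or preparation difference between the genotypes under L-Glu was not tested.

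For the comparisons of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. Only 1 split, the real one, called as many genes in each. The real split called 8946 genes for L-Glu in Col-0 and the highest other 0. It called 9592 in sid2 and the highest other 0, 37 between genotypes under urea and the highest other 2, and 1983 under L-Glu and the highest other 1. Where the numbers paired the libraries, the other splits that parted all pairs called 0 genes in both comparisons. Each other split mixed libraries of the compared groups. Any difference between these groups then enters the spread and lowers the count, so the low counts of the other splits decide little.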

How the results depend on the processing

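The scaling of each library to one total was chosen after the data were seen. Under all 26 alternatives, the counts for L-Glu against urea stayed within 1.5 times the reported ones, and the correlation of effects ranged from 0.934 to 0.953 over the omitted libraries. Without 1 library these counts were 8135 to 8875 in Col-0 and 8812 to 9947 in sid2. The interaction count (291) was 9 to 367 without 1 library, 453 with a pseudocount of 5, 153 with quantile normalization, 143 without the trend and 627 with library weights. The count under urea (37) was 13 to 37 without 1 library, 20 with a pseudocount of 5, 5 with the urea libraries alone, 12 without the trend, 67 with library weights and 60 at one total. The count under L-Glu (1983) was 792 to 2649 without 1 library and 895 with a fold limit of 2. With the replicate block the 5 counts were 9160, 9775, 426, 49 and 2360, and with the urea libraries alone, paired by this block, 1 gene was called. BGLU23 turned to -0.15 and, in sid2, FER1 to -0.48 with quantile normalization, and MYB36 to -0.01 and PP2AA3 to -0.44 at one total, in Col-0. Of the other results of named genes, 12045 kept their side of the threshold, 309 lost it and 63 gained it. For lists these were 2833, 72 and 43. Fry called 19, 17, 1, 7 and 8 of the 22 lists, against 10, 9, 2, 14 and 6 by camera. The counts are not alike, as fry asks whether a list changes at all and camera whether it changes more than other genes. Most genes were called for L-Glu against urea, so the fry calls there say little about the lists in particular. Camera calls held without any one library for 10 of 10, 9 of 9, 1 of 2, 9 of 14 and 5 of 6 lists. A fold limit can only lower a count, and for the other changes the cause was not tested. The filter on low values removed 0 genes, so its omission says nothing, and the alternatives for raw counts (edgeR and DESeq2) were not run. The read depth is unknown, so what it limits was not assessed.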

Other observations

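All tests in this part except the medians of the photosynthesis and root marker lists, as well as the protein families and the genes named outside the rule, were chosen after the results were seen.

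Besides the fixed lists 13 protein families were tested. Of their camera calls only that of the WRKY family in Col-0 held with an estimated correlation. This family shares members with the fixed lists, such as WRKY30, WRKY46 and WRKY54, so its call is not separate from theirs. In Col-0 29 of 36 measured WRKY transcription factor genes rose with L-Glu and 3 fell, or 30 and 3 when adjusted over the family alone, with a median log2 fold change of 2.22 (camera adjusted p = 3.08e-09, adjusted p = 0.0391 with an estimated correlation). WRKY51 changed by 7.37 and WRKY28 by 5.64. In sid2 24 rose and 4 fell (camera adjusted p = 5.12e-06, adjusted p = 0.140 with an estimated correlation). Of 71 TIR-NBS-LRR genes, which encode intracellular immune receptors, 54 rose and 5 fell in Col-0, or 55 and 5 over the family alone (camera adjusted p = 2.34e-11, adjusted p = 0.324 with an estimated correlation). Of 174 nuclear genes of ribosomal proteins, plastid ones included, 7 rose and 117 fell in Col-0, or 7 and 120 over the family alone (camera adjusted p = 3.61e-10, adjusted p = 0.324 with an estimated correlation). In sid2 20 rose and 48 fell, or 16 and 44 over the family alone (camera adjusted p = 0.0417, adjusted p = 0.742 with an estimated correlation). Among them the plastid ribosomal protein gene RPS1 changed by -4.03 in Col-0 and -3.88 in sid2. The interaction had a median of 0.66 for this family, with 9 genes called upwards and 0 downwards, or 59 and 0 over the family alone (camera adjusted p = 6.34e-16, adjusted p = 0.576 with an estimated correlation). Under L-Glu 65 of these genes were higher in sid2 and 0 lower, or 83 and 1 over the family alone (camera adjusted p = 5.09e-16, adjusted p = 0.492 with an estimated correlation). Of 59 chloroplast-encoded genes, 24 fell in Col-0, or 16 over the family alone (camera adjusted p = 0.00499, adjusted p = 0.686 with an estimated correlation). In sid2 41 fell, or 42 over the family alone (camera adjusted p = 5.10e-06, adjusted p = 0.601 with an estimated correlation), and 0 rose in either. The interaction of the chloroplast-encoded genes ran the other way than that of the ribosomal family, with a median of -0.71 and 0 genes called (camera adjusted p = 3.39e-05, adjusted p = 0.773 with an estimated correlation). The organelle share was 0.666% in Col-0 urea library 1, against 1.55% and 1.25% in its group. In Col-0 L-Glu library 2 it was 0.858%, against 0.385% and 0.572%. Both make the fall in Col-0 smaller, and no values of this family without these libraries are given here. The medians of these 4 families kept their direction in Col-0 and sid2 under median-ratio rescaling, quantile normalization and one total per library, and under the removal of organelle genes for the 3 nuclear families.

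Camera also called 4 other families in Col-0. The families were matched by product name, and some also hold related genes. The calmodulin-related set includes CAMBP25 and CPK2, and the proteasome-related set FUS12 and EER5. Of 35 calmodulin-related genes 25 rose and 6 fell (adjusted p = 6.52e-06, 0.324 with an estimated correlation). Of 33 glutathione S-transferase genes 19 rose and 7 fell (0.0122, 0.447), and of 43 proteasome-related genes 3 rose and 20 fell (0.0438, 0.444). Of 75 UDP-glycosyltransferase genes 37 rose and 14 fell (0.0122, 0.444), but their median of 0.51 turned to -0.12 at one total per library. Further camera calls were those of calmodulin-related genes (8.37e-05) and TIR-NBS-LRR genes (2.43e-10) in sid2 and of ribosome biogenesis in the interaction (0.00282). Under urea the TIR-NBS-LRR genes were called as lower in sid2 (0.0394, 0.883 with an estimated correlation), with 0 single genes called. Under L-Glu the WRKY genes (0.0240, 0.492) and the chloroplast-encoded genes (0.000699, 0.839) were called as lower. Of these, 5 WRKY genes were lower and 1 higher, and 2 chloroplast-encoded genes were lower and 0 higher. Ribosome biogenesis was called as higher (0.00221, 0.492), with 10 genes higher and 0 lower.

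WRKY54 was low in all sid2 libraries, at 5.68 to 12.4, while its measured neighbours differed little between genotypes. CTEXP on one side differed by -0.06 under urea and -0.06 under L-Glu, and AT2G40760 on the other by -0.09 and -0.07. UGT74F2, an SA glucosyltransferase gene, was lower in sid2 by -1.28 under urea (adjusted p = 0.00791) and -2.05 under L-Glu (adjusted p = 2.03e-05), with no overlap between the groups in either. Its call under urea was ended by 2 of the 12 omissions.

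With limits of 0.5 and at least 8 genes, a run of 16 neighbouring measured genes on chromosome 3, from BET10 (AT3G01770) to AT3G01980, was higher in sid2 under urea, with a median log2 difference of 1.02 (SD 0.322), and 6 of them were called. In the L-Glu libraries, which did not define the run, the median was 0.828 (SD 0.373), all 16 genes had higher estimates and 9 were called. Against a chance run, only 1 of 14713 other windows of as many genes was as high, a window on chromosome 5 from 2-Cys Prx B (AT5G06290) to AT5G06550 at 0.890 that was also raised under urea (0.723), so that it may be no chance window either, and against the scaling of the libraries, the 32 flanking genes had a median of 0.041 under urea. A gain of copies of the segment in the sid2 line is a candidate explanation, as a hypothesis, since it would give a log2 difference of about this size in both treatments. No DNA data were used here, and other differences between the lines were not tested.

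The fall of the nuclear photosynthesis genes in Col-0 (median -4.73) was weighed against technical explanations. A factor per library would move all genes alike, but the list median lay -4.68 from the median of all genes, which argues against the scaling as the source of the whole fall. The changes had an SD of 1.56 across members against a median SE of 0.251, from -2.83 for LHCB2.1 to -8.84 for RBCS2B. This spread cannot decide on a lower share of shoot RNA. Members expressed to different degrees in the remaining tissue would then fall by different factors. The root cell type markers had a median of -0.06 (SD 0.779). A response of these genes to L-Glu or to urea, a lower share of shoot RNA with L-Glu, or both may account for the pattern. This stays a hypothesis.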
